A study of Mus musculus with 2 samples.

How the data were processed

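The samples were 2 biological replicates of E13.5 mouse midbrain, per the labels, each with H3K4me2 ChIP-seq. They formed 1 group, so nothing was paired or blocked and no conditions were compared. The authors supplied 4 peak lists in narrowPeak form on mm10: 1 for each replicate, 1 called on the pooled replicates and 1 replicated list. The deposited README texts say that the pooled list was derived from the alignments of both replicates and the replicated list from the pooled and both replicate lists. The peak caller, the aligner, the control used for each list and the rule for keeping a replicated peak are not given in the sources used here. Enrichment, the peak's signal value in the deposited lists, is a ratio that the authors' caller computed, and relative to what is not stated. The deposited lists also hold the authors' -log10 p and -log10 q for each peak. The lowest -log10 p was 2.00 in replicate 1 and 2.44 in the replicated list, and 99.9% of replicated peaks had a -log10 q of at least 2. Enrichment is the authors' own value and was compared within a list, except in the rank correlation between the replicates' lists. Signal tracks were not used here. Read depth is unknown, so no interval that needs it is given. Wilson intervals (95%) on shares of peaks cover counting error only, and neighbouring peaks are not independent.

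Gene models were the comprehensive GENCODE vM21 annotation on GRCm38, the assembly of mm10, with 55413 genes, of which 21938 were protein-coding on the 21 assembled chromosomes. Peaks outside those chromosomes were left out of all gene comparisons. A gene was marked when a replicated peak overlapped the 1 kb to either side of the 5′ end of its record. That end can lie far from the start that is most used, so the starts of all coding transcripts were checked for unmarked genes that are named. Marked domains were replicated peaks joined across gaps of less than 1 kb, and a gene's domain was the longest that reached within 1 kb of its 5′ end. Peaks whose midpoint was over 2.5 kb from every annotated start were distal and were assigned to the nearest protein-coding 5′ end, which is a rule of distance and not evidence of regulation. Peak positions were also compared with 100 random placements within chromosomes.

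The 16 gene lists, the 10 motifs, the tests and the rule for named genes were fixed before the data were examined. Symbols or patterns gave 1410 list members, of which 1409 matched a gene; Ahsp did not. Lists were compared with all other protein-coding genes, or all other marked genes for domain length, by two-sided Fisher's exact test. Distal counts were compared with 10000 random lists of the same size (two-sided permutation test). Motifs on either strand were compared between the central 500 bp of distal peaks and the nearest peak-free 500 bp window 5 kb away (two-sided exact McNemar test). P-values were adjusted by Benjamini-Hochberg over the 16 lists or the 10 motifs, with a threshold of 0.05. In the other observations, family p-values were adjusted over the families tested, and p-values not called adjusted were left unadjusted. They measure differences between sets of genes or sequences within this tissue, and genes and peaks are not replicates. Values with an SD are means over the replicates' own lists, n = 2.

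The named genes were, for each list, the 2 members with the longest domain and every unmarked member where there were 5 or fewer. To these were added the 10 protein-coding genes with the longest domains, the 10 with the most distal peaks, and Th, En1, Otx2, Foxg1 and Hoxa2, with ties taken in order of name. Rapgef5, Sox9, Nt5c3, Zfhx3, Klc3, Gm20388, Myh7, Gypa, Rps11 and Rpl35 were named after their values were seen, as were all genes and families in the other observations.

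Alternatives planned for the choices were each replicate's own list in place of the replicated list, the pooled list, and peaks at or above the list's median enrichment or with a -log10 q of at least 2. Others were an overlap of 1 bp or of 50% of both peaks, correlation by -log10 p or over peaks with 1 match in each replicate, windows of 2.5 kb, any coding start, no joining or joining under 3 kb, the longest 10%, and 5 kb from every start. The matched alternatives used 10 equal groups of genes by observed over expected CpG within 500 bp of the start or by the distance between neighbouring starts, and pairs within 5 GC points. Matching of the domain-length lists on CpG number within 5 kb and on spacing was added after the data were seen.

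The steps were tested on simulated data with 20 runs each for lists and motifs. For promoter marking, all 80 changed lists were called and 2 of 240 unchanged lists. For distal peaks, 79 of 80 changed lists were called and 1 of 240 unchanged lists. For motifs, all 40 planted motifs were called and 5 of 160 unchanged ones, and all 2563 simulated overlaps were found. The simulated changes were larger than most of the real differences, and simulated peaks and flanks did not differ in GC content. These counts therefore do not show how often small differences would be found. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, pysam 0.24.0 and samtools 1.23.1.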

Results

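Dimethylation of histone H3 at lysine 4 (H3K4me2), a chromatin mark of gene starts and enhancers, was mapped by ChIP-seq in midbrain tissue of mouse embryos at embryonic day 13.5. The strain was B6NCrl and each tissue pool held male and female embryos. The series held 1 group of 2 biological replicates from separate biosamples, so no comparison of conditions was possible. The questions addressed were where the mark lay, how far the replicates gave the same regions, and which groups of genes carried it. The files give peaks and no read counts, so the read depth of each replicate is unknown. All positions are on mm10.

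The replicates marked nearly the same strong regions and differed in weak ones. The replicate 1 list held 49659 peaks covering 54.1 Mb, with a median width of 627 bp. The replicate 2 list held 47456 peaks covering 53.0 Mb, with a median width of 668 bp. The authors' replicated list, which served as the peak set for all gene comparisons, held 37511 peaks covering 56.5 Mb. Of these, 37499 lay on assembled chromosomes, where they covered 2.07% of the sequence, 1061 of them on chromosome X and 9 on chromosome Y. The median width of replicated peaks was 1060 bp and their quartiles were 565 and 2043 bp. Each of the 37499 peaks had the coordinates of a peak in the list called on pooled replicates. The 11989 pooled peaks that were not carried into the replicated list had a median enrichment of 2.67, against 11.8 for the replicated peaks.

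Of the 49644 replicate 1 peaks on assembled chromosomes, 36707 were covered over at least 50% of their length by replicate 2 peaks, a share of 73.9% (95% Wilson interval 73.6 to 74.3). In the other direction 37206 of 47444 replicate 2 peaks were covered, a share of 78.4% (95% Wilson interval 78.0 to 78.8). Random placement of the other list gave means of 1.88% and 1.91%, with a highest value of 2.05% in each direction. With replicate 1 peaks split into 5 equal groups by enrichment, 29.99% of the weakest group were covered and 100% of the strongest. Uncovered peaks had median enrichments of 3.15 in replicate 1 and 3.14 in replicate 2, against 12.7 and 11.8 for covered peaks. The replicates shared 47.4 Mb of the 59.7 Mb that either covered, a ratio of 0.793. Across 35368 replicated peaks that touched peaks of both replicates, the Spearman correlation of enrichment was 0.931. That correlation is across peaks of 1 pair of samples, and peaks are not independent replicates. Peaks listed in only 1 replicate did not enter it. Of the 37499 replicated peaks on assembled chromosomes, 32861 (87.6%) were covered over at least 50% of their length by the peaks of each replicate.

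**Figure D1:**
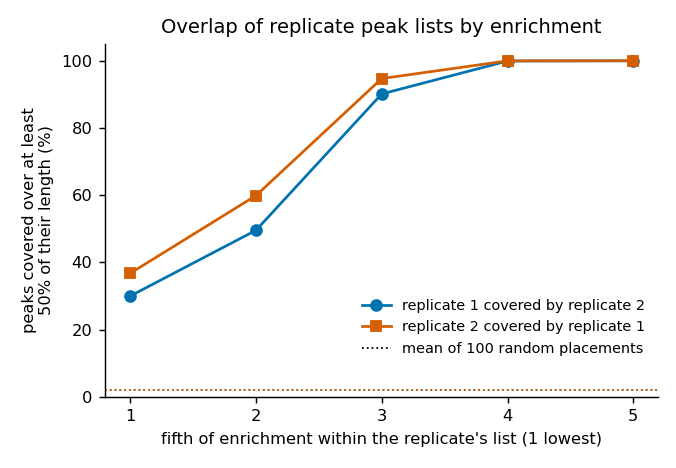
Percentage of each replicate's peaks covered over at least 50% of their length by the other replicate's peaks (y axis) in 5 equal groups by enrichment within the replicate's own list (x axis, 1 lowest). Blue circles are replicate 1, orange squares replicate 2, and the dotted lines the means of 100 random placements (1.88% and 1.91%). Coverage runs from 29.99% of replicate 1 peaks in the lowest group to 100% in the highest.

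H3K4me2 was concentrated at gene starts. Of the replicated peaks, 46.4% had their midpoint within 1 kb of an annotated transcription start site (95% Wilson interval 45.9 to 46.9), against a mean of 6.15% for random placement. In the replicates' own lists that share was 41.3% ± 1.07 (SD, n = 2). Peaks at start sites were also the longest and strongest, with a median width of 1827 bp and a median enrichment of 31.5, and they made up 62.4% of the covered sequence. Introns held 28.4% of peaks against 39.1% for random placement, and the replicates' own lists gave 32.9% ± 0.634 (SD, n = 2). Intergenic sequence held 20.4% against 51.4%, and the replicates' own lists gave 20.5% ± 0.468 (SD, n = 2). Exons held 4.77% against 3.29%, and the replicates' own lists gave 5.21% ± 0.0328 (SD, n = 2). Intronic peaks had a median width of 672 bp and a median enrichment of 4.75. When only peaks at or above the list's median enrichment were kept, the share within 1 kb of a start site was 75.2%.

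**Figure D2:**
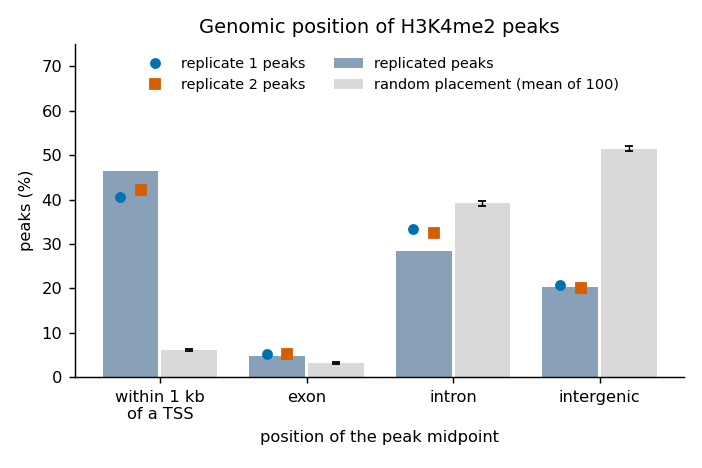
Percentage of peaks (y axis) whose midpoint lies within 1 kb of a transcription start site, in an exon, in an intron or in intergenic sequence (x axis). Blue bars are the replicated list, circles and squares the replicates' own lists, and grey bars the mean of 100 random placements, with error bars from their lowest to their highest value. The start-site share is 46.4% against 6.15% for random placement.

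Of 21938 protein-coding genes, 13947 (63.6%) had a replicated peak within 1 kb of the 5′ end of the gene record, here called marked. The share in the replicates' own lists was 63.8% ± 0.0870 (SD, n = 2), and 13891 genes were marked in both. Of 10153 long noncoding RNA genes, 2922 (28.8%) were marked, with 29.5% ± 0.279 in the replicates' own lists (SD, n = 2). Of these 2922 genes, 1680 shared their domain with a protein-coding gene and 1242 did not. Marking followed the CpG content of the start. With protein-coding genes split into 10 equal groups by observed over expected CpG at the start, 1.87% of the lowest group and 99.5% of the highest were marked.

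Midbrain and forebrain patterning, neural progenitor, pan-neuronal and ribosomal protein genes were marked at their starts more often than other genes, and muscle, liver, microglial and olfactory receptor genes less often. Of these differences, only the forebrain, pan-neuronal and olfactory receptor ones also passed against genes of like CpG content, as given below. All 22 midbrain patterning genes were marked, among them En1 and Otx2, homeodomain factors needed to form the midbrain, in each replicate as in the replicated list (adjusted p = 0.000255, Fisher's exact test). All 22 forebrain patterning genes, such as Foxg1 and Lhx2, were also marked (adjusted p = 0.000255, Fisher's exact test). Neural progenitor genes were marked in 17 of 18 cases (adjusted p = 0.00965) and pan-neuronal genes in 18 of 19 (adjusted p = 0.00646, Fisher's exact tests). Cytosolic ribosomal protein genes and their paralogs were marked in 72 of 76 cases (adjusted p = 1.62e-09, Fisher's exact test). Each of these shares was compared with the 63.5% of all other protein-coding genes, and each count was the same in both replicates.

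Fewer genes than in the rest of the genome were marked in the lists for muscle and heart, 3 of 14 (adjusted p = 0.00369), and for liver, gut and pancreas, 2 of 15 (adjusted p = 0.000291, Fisher's exact tests). Microglia and leukocyte genes were marked in 2 of 12 cases (adjusted p = 0.00324, Fisher's exact test). These were P2ry12 and Tmem119, microglial surface proteins, with domains of 0.543 and 0.455 kb. The Tmem119 domain measured 0.193 kb ± 0.00424 in the replicates' own lists (SD, n = 2). Of 1093 olfactory receptor genes, known chiefly from the olfactory epithelium, 2 were marked, Olfr658 and Olfr1033, and Fisher's exact test gave a p below what the arithmetic returns (0). The marked liver and gut genes were Apob, with a domain of 0.436 kb, and Cdx2, with 0.308 kb, which replicate 1 alone had in its own list. Among muscle genes, Myod1, a regulator of muscle fate, had a domain of 1.98 kb. The 0.894 kb peak counted for Myh7, a cardiac myosin gene, lay wholly upstream of the gene. The 1.08 kb peak near Ckm, the muscle creatine kinase gene, lay outside the gene and at the start of its neighbour Klc3.

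Counts in the remaining lists did not pass the threshold in Fisher's exact test. They were 15 of 17 for the other midbrain neuron types (adjusted p = 0.0631), 9 of 12 for dopaminergic neurons (0.554), 6 of 15 for glia (0.0865) and 6 of 11 for endothelium (0.554, Fisher's exact tests). Mesenchyme and pericyte genes gave 11 of 14 (adjusted p = 0.347), erythroid genes 3 of 10 (0.0631) and Hox genes 22 of 39 (0.463, Fisher's exact tests). Erythroid genes with the longest domains were Epor, the erythropoietin receptor gene, with 2.66 kb, and Klf1, with 1.69 kb, and the third was Gypa, with 1.22 kb. The endothelial receptor gene Kdr had 2.78 kb and the transcription factor gene Erg 2.08 kb.

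Some unmarked list members were marked at another coding start, since the 5′ end of the gene record is its most distal transcript end. Th, the gene of the rate-limiting enzyme of dopamine synthesis, had a peak on chromosome 7 from 142899248 to 142899813 at 1 of its 3 coding starts, 31.1 kb from the 5′ end of the record. Gad1, which encodes a GABA-synthesising enzyme, was marked at 4 of its 5 coding starts, and Rbfox3, which encodes the neuronal antigen NeuN, at 4 of 7. Notch1 was marked at 1 of 2 coding starts, in a peak on chromosome 2 from 26496246 to 26505043, and Rpl17 at 1 of 2. No coding start was marked in Ddc, whose nearest peak was 29.4 kb from its 5′ end, in Aldh1a1, 148 kb away, or in Phox2b, a motor neuron regulator, 2.47 kb away. The unmarked endothelial genes were Cdh5, Emcn, Pecam1, Tek and Tie1, of which replicate 2 alone listed a peak at Tie1. The unmarked mesenchymal genes were Acta2, Col3a1 and Lum, and the other unmarked ribosomal genes were Rpl10l, Rpl39l and Rpl3l. Unmarked members marked at another coding start also numbered 3 of 9 for glia and 2 of 11 for muscle and heart. They numbered 1 of 10 for microglia and leukocytes and 1 of 17 for Hox genes. Counting any coding start, the difference for the other midbrain neuron list was 28.0 percentage points (adjusted p = 0.0283, Fisher's exact test). The other 15 lists then kept their direction and their side of the threshold.

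Several of these differences did not pass against genes of like CpG content. Random genes matched to the midbrain patterning list on observed over expected CpG were marked in 93.2% of cases (adjusted permutation p = 0.339). With all 22 members marked the list was at its maximum, so this comparison could not show an excess. The other list shares that no longer passed were neural progenitor, with 87.2% expected (adjusted permutation p = 0.518), ribosomal protein, 92.6% (0.592), microglia, 23.2% (1), muscle and heart, 35.7% (0.423), and liver, gut and pancreas, 35.3% (0.0826). Forebrain patterning genes stayed above the 86.5% expected (adjusted permutation p = 0.0352) and pan-neuronal genes above 75.1% (0.0213). Hox genes, at 56.4%, lay below the 89.6% expected (adjusted permutation p = 0.0016), and olfactory receptors, at 0.183%, below 6.39% (0.0016). With only peaks at or above the median enrichment, the forebrain difference was 3.52 percentage points (adjusted p = 0.830), the Hox difference -39.7 (adjusted p = 3.08e-06) and the glia difference -33.5 (adjusted p = 0.0233, Fisher's exact tests). With a window of 2.5 kb the muscle and heart difference was -15.4 points (adjusted p = 0.325, Fisher's exact test), and that of the other midbrain neuron list 28.8 points (adjusted p = 0.0188, Fisher's exact test).

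Among the 10 protein-coding genes with the longest marked domains, all but Ptch1 encode transcription factors. Peaks less than 1 kb apart were joined, and the longest 5% of domains at marked genes were those of at least 6.64 kb, at 701 genes, against a median of 2.68 kb. The longest domain, 40.4 kb on chromosome 13 from 78171027 to 78211421, held Nr2f1, an orphan nuclear receptor gene, and measured 40.3 kb ± 0.159 in the replicates' own lists (SD, n = 2). Zic1 and Zic4 shared a domain of 38.6 kb, which in replicate 2's own list measured 23.9 kb. Pou3f3 had 32.0 kb, Sox2 31.7 kb, Nr2f2 30.7 kb, Meis2 24.9 kb, Pax6 24.9 kb and Ebf3 23.8 kb. Ptch1, which encodes the Sonic hedgehog receptor, had 23.7 kb. The Sox2 domain measured 20.8 kb in replicate 1's own list.

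Long domains were more frequent in 5 lists than among other marked genes. Of 22 marked midbrain patterning genes, 16 were in the longest 5%, against 4.92% of other marked genes (adjusted p = 1.27e-15, Fisher's exact test), with a median of 11.7 kb. In the replicates' own lists the share was 65.9% ± 3.21 (SD, n = 2). Meis2 and Pax5 were the longest, Pax5 with 21.7 kb on chromosome 4 from 44694192 to 44715938. Genes of the other midbrain neuron types reached 11 of 15 (adjusted p = 4.35e-11, Fisher's exact test), led by Gata3, a GABAergic neuron regulator, with 22.9 kb, and Lhx1 with 22.8 kb. The Gata3 domain also reached the starts of 4930412O13Rik and 9230102O04Rik, and the Lhx1 domain that of Aatf. Neural progenitor genes reached 11 of 17 (adjusted p = 2.40e-10), led by Sox2 and Pax6, and forebrain patterning genes 11 of 22 (adjusted p = 8.13e-09, Fisher's exact tests), led by Lhx2 with 22.9 kb and Six3 with 20.8 kb. Pan-neuronal genes reached 6 of 18 (adjusted p = 0.000557, Fisher's exact test), led by Myt1l with 14.4 kb and Celf4 with 12.3 kb. In the replicates' own lists the midbrain count was 14 in replicate 1 and 15 in replicate 2, the pan-neuronal count 7 and 6, and the other counts were 11 in each. Marked genes matched on CpG number within 5 kb gave higher expected shares, which all 5 lists still exceeded. They were 23.0% for midbrain patterning, 18.1% for other midbrain neuron, 17.4% for neural progenitor, 21.1% for forebrain and 7.69% for pan-neuronal genes.

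No other list passed. The 9 marked dopaminergic neuron genes had a median of 2.16 kb and none in the longest 5%, with Slc18a2, the vesicular monoamine transporter gene, at 3.13 kb and Ret at 2.49 kb. None of the 22 marked Hox genes was in the longest 5% (adjusted p = 1, Fisher's exact test). With 22 genes, even a count of 0 could not pass as fewer. The Hox median was 0.752 kb, and the longest were Hoxa1 with 1.52 kb and Hoxd8 with 1.49 kb. In the replicates' own lists the Hox median was 0.501 kb over 24 marked genes in replicate 1 and 0.719 kb over 21 in replicate 2. Glia had 1 of 6, which was Olig2, a regulator of the oligodendrocyte lineage, with 10.5 kb, ahead of Pdgfra with 4.39 kb (adjusted p = 0.710, Fisher's exact test). Ribosomal protein genes had 4 of 72, against 5.02% of other genes (adjusted p = 1, Fisher's exact test). These were Rps18, Rpl13a, Rps11 and Rpl35, and Rps18 and Rpl13a, with 7.55 kb each, lay in domains that reached other gene starts. In replicate 1's own list the Rps18 domain measured 4.66 kb. The endothelial, microglial, erythroid, mesenchymal, muscle, liver and olfactory receptor lists had 0 in the longest 5% (adjusted p = 1 for each, Fisher's exact test). Each had too few marked members for 0 to pass as fewer. Among mesenchymal genes the longest were Prrx1 with 3.91 kb and Twist1 with 3.69 kb.

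Domain length depended on joining. Without it a gene was given the longest single peak that reached within 1 kb of its 5′ end. The rest of the domain can hold longer peaks. The peak at the 5′ end was 8.06 kb at Nr2f1, 12.3 kb at Zic1, 16.9 kb at Pou3f3 and 7.29 kb at Nr2f2. It was 4.16 kb at Sox2, 10.04 kb at Pax6, 3.49 kb at Pax5, 2.06 kb at Gata3 and 11.2 kb at Otx2. The pan-neuronal count no longer passed when peaks closer than 3 kb were joined (adjusted p = 0.604, Fisher's exact test).

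**Figure D3:**
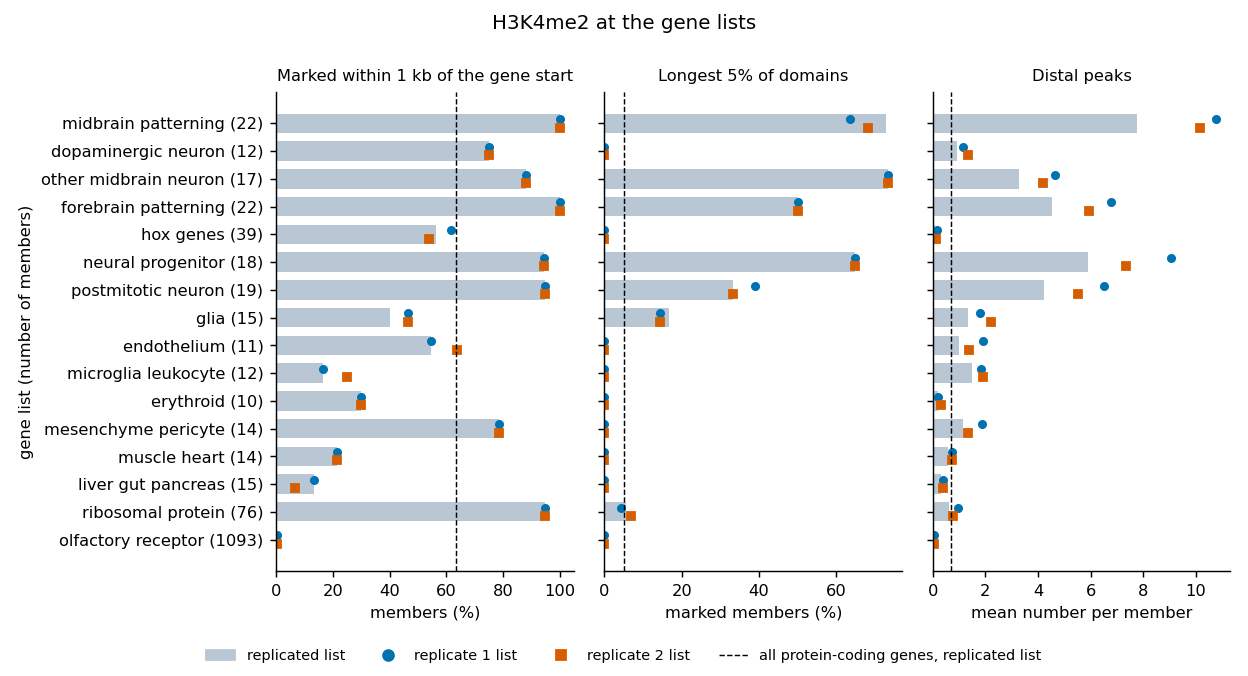
H3K4me2 at the 16 gene lists (y axis, with the number of members), as the percentage of members marked within 1 kb of the gene start, the percentage of marked members among the longest 5% of domains, and the mean number of distal peaks per member (x axes of the 3 panels). Bars are the replicated list, circles replicate 1's own list and squares replicate 2's own list. Dashed lines are all protein-coding genes in the outer panels. In the middle panel the dashed line is the 5% of marked genes set by definition. Midbrain patterning genes reach 100%, 72.7% and 7.77, and olfactory receptors 0.183%, 0% and 0.0329.

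The regulators En1 and Otx2 stood within long blocks of marking. At En1 the domain ran on chromosome 1 from 120594848 to 120611216, 16.4 kb, and measured 16.4 kb ± 0.0530 in the replicates' own lists (SD, n = 2). It held the whole En1 gene. The Otx2 domain ran on chromosome 14 from 48654303 to 48675666, 21.4 kb, and held the whole gene, with 21.3 kb ± 0.188 in the replicates' own lists (SD, n = 2). Foxg1, a factor of the telencephalon, had a domain of 2.27 kb on chromosome 12 from 49382589 to 49384863, with 2.17 kb ± 0.503 in the replicates' own lists (SD, n = 2). Hoxa2, a hindbrain patterning gene, had no peak at its start, and the nearest peak, at the start of Hoxa1, lay 5.36 kb away. Over 80 kb around each start, replicated peaks covered 31.5% at En1, 31.3% at Otx2, 9.38% at Foxg1 and 5.08% at Hoxa2. At Foxg1 the replicates' own peaks covered 6.59% in replicate 1 and 11.9% in replicate 2.

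**Figure D4:**
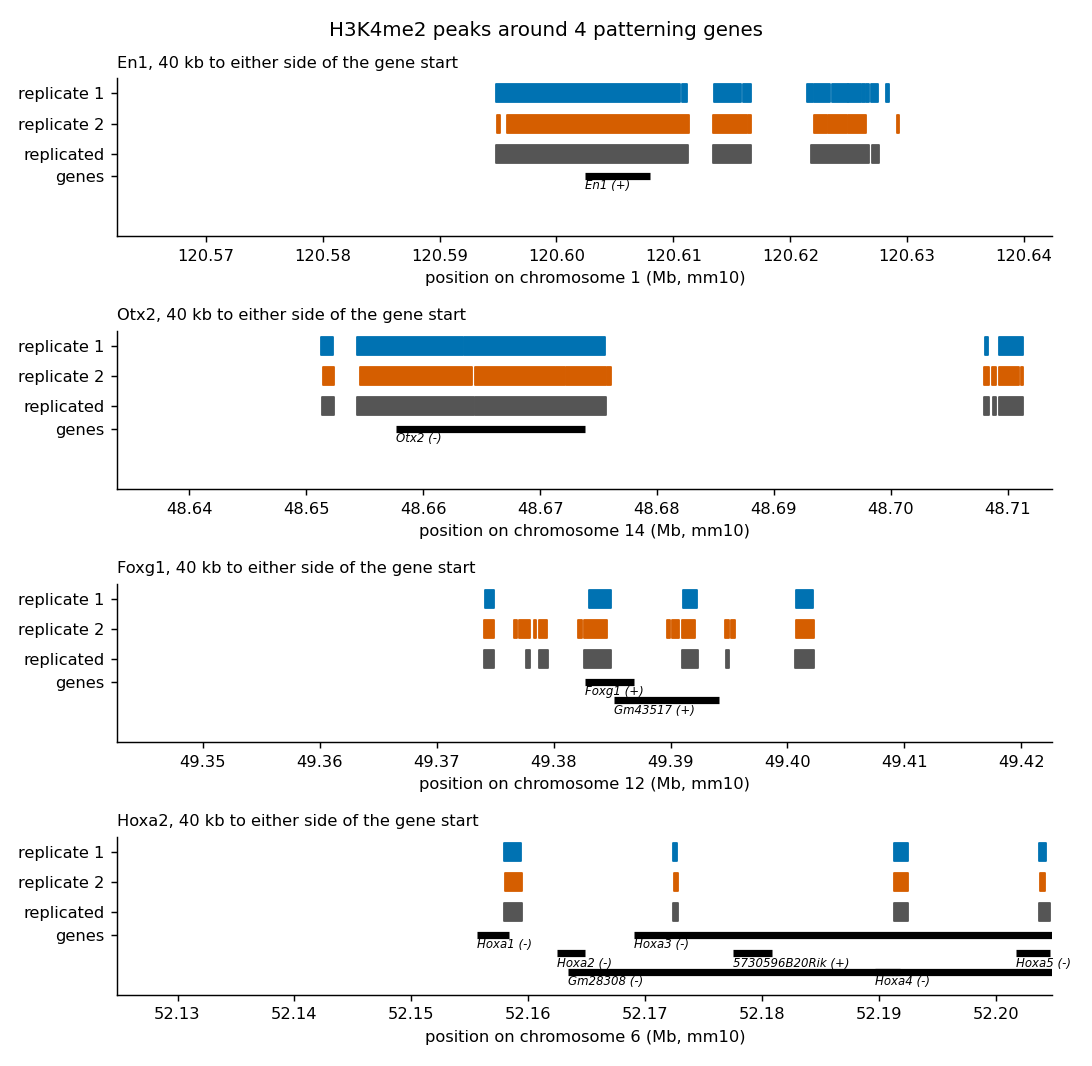
Positions of H3K4me2 peaks in 80 kb around the starts of En1, Otx2, Foxg1 and Hoxa2 (x axes, Mb on mm10), with rows for replicate 1, replicate 2, the replicated list and the annotated genes with their strands. Boxes are peaks and black bars genes. Replicated peaks cover 31.5%, 31.3%, 9.38% and 5.08% of the 4 windows.

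Distal peaks were most numerous near genes of the same 5 lists. They were counted before joining, so parts of a gene's long domain can be among its distal peaks, and the count is not independent of domain length. The count also depends on how peaks were split. Around En1, replicate 1 had 12 peaks over 31.1% of 80 kb, and the replicated list 4 peaks over 31.5%. Of the replicated peaks, 15545 (41.5%) lay more than 2.5 kb from every annotated start site, with a median enrichment of 4.92. Assigned to the nearest protein-coding gene start, they gave a mean of 0.709 per gene, and 6410 genes had at least 1. Midbrain patterning genes had a mean of 7.77 distal peaks (adjusted permutation p = 0.00064), with 10.5 ± 0.450 in the replicates' own lists (SD, n = 2). Otx2 had 14, Meis2 12 and En1 6, and in the replicates' own lists Otx2 had 19.5 ± 2.12, Meis2 16.5 ± 0.707 and En1 9.5 ± 2.12 (SD, n = 2). Neural progenitor genes had a mean of 5.89, with 17 at Sox2, forebrain patterning genes 4.55, with 10 at Six3, and pan-neuronal genes 4.21, with 20 at Celf4 and 11 at Myt1l (adjusted permutation p = 0.00064 for each). The replicates' own lists held more distal peaks, with 24.5 ± 4.95 at Sox2, 15 ± 1.41 at Six3, 31 ± 1.41 at Celf4 and 18 ± 1.41 at Myt1l (SD, n = 2). Before adjustment, p for these 4 lists was 0.0002, the smallest that the permutations can give. Genes of the other midbrain neuron types had a mean of 3.29 (adjusted permutation p = 0.00213).

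Fewer distal peaks than in random lists lay near Hox genes, with a mean of 0.103 (adjusted permutation p = 0.0032), and near olfactory receptor genes, with 0.0329 (adjusted permutation p = 0.00064). The Hox mean was 0.179 in replicate 1's own list and 0.128 in replicate 2's. The remaining lists did not pass, and their means were 1.33 for glia, 1.5 for microglia, 1.14 for mesenchyme, 1 for endothelium and 0.917 for dopaminergic neurons. In the replicates' own lists the glia mean was 2.2 in replicate 2, and in replicate 1 the mesenchyme mean was 1.86 and the endothelium mean 1.91. The lowest of these lists had 0.632 for ribosomal protein, 0.571 for muscle and heart, 0.333 for liver, gut and pancreas and 0.2 for erythroid genes (adjusted permutation p between 0.327 and 0.997 for these 9 lists). Against genes with like spacing to their neighbours, the 5 lists with more distal peaks stayed above expectation, such as the midbrain list against 1.72, while the Hox mean lay below its expectation of 0.150 without passing the threshold (adjusted permutation p = 0.905). With only peaks at or above the median enrichment, the excess over random lists was 1.65 for midbrain patterning, 1.37 for neural progenitor, 0.662 for pan-neuronal, 0.554 for forebrain patterning and 0.461 for the other midbrain neuron list. The largest of the adjusted permutation p values for those 5 lists was 0.0181. In replicate 1's own list the excess was 8.04 for neural progenitor and 5.51 for pan-neuronal genes, against 5.19 and 3.51 in the replicated list.

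Among single protein-coding genes, Pmfbp1 had the most distal peaks, 42, but its own start was unmarked and 24 of these lay in the body of Zfhx3, a transcription factor gene whose record starts 1.55 Mb away. Adgrl2, a latrophilin receptor gene, had 33, Efna5, an ephrin ligand gene, 30, of which 23 lay within it, and Zfp608 30. The transcription factor genes Bcl11a and Pbx1 had 24 each, Sox4 23 and Ebf1 22, and the corepressor gene Bcor 22. Gins2 had 22, all within the body of the annotated gene Gm20388. Nr2f2, Rapgef5 and Sox9 also had 22 and came after Bcor, Ebf1 and Gins2 by name alone. In the replicates' own lists Efna5 had 51 ± 5.66 and Gins2 37.5 ± 3.54 (SD, n = 2).

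Distal peaks held more of several transcription factor motifs than the sequence beside them. Over 15160 distal peaks paired with a peak-free window 5 kb away, the E-box CAGCTG occurred in 34.2% of central 500 bp windows against 20.8% of flanks (adjusted p = 1.99e-150, exact McNemar test). The ETS motif CCGGAA occurred in 11.8% against 4.69% (adjusted p = 7.38e-114) and the RFX motif GTTGCYATGG in 2.23% against 0.462% (adjusted p = 1.10e-42, exact McNemar tests). Smaller differences passed for the homeodomain motif TAATTA, 14.4% against 13.3% (adjusted p = 0.00718), and the FOX motif TGTTTAC, 7.37% against 6.55% (0.0065, exact McNemar tests). The NFI motif TGGCANNNTGCCA occurred in 0.224% against 0.0858% (adjusted p = 0.00515, exact McNemar test). The GATA motif AGATAA was less frequent in peaks, 21.7% against 25.3% (adjusted p = 2.30e-13), as was the AP-1 motif TGASTCA, 7.51% against 8.65% (0.000668, exact McNemar tests). The E-box CAGATG, 34.8% against 34.5% (adjusted p = 0.610), and the SOX motif ACAAWG, 54.2% against 53.4% (0.214), did not pass in exact McNemar tests.

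Mean GC content was 50.4% in peaks and 44.7% in flanks, and matching it moved several motifs. Among the 6665 pairs within 5 GC points the homeodomain difference was 6.72 percentage points (adjusted p = 1.21e-28) and the SOX difference 5.12 points (5.54e-09, exact McNemar tests). The GATA motif then turned to 2.37 points more in peaks (adjusted p = 0.00148, exact McNemar test). The CAGCTG difference was 7.64 points (adjusted p = 9.24e-23), the FOX difference 2.06 points (4.23e-06) and the AP-1 difference -2.21 points (7.51e-06, exact McNemar tests). The CAGATG difference was -0.765 points (adjusted p = 0.361, exact McNemar test).

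**Figure D5:**
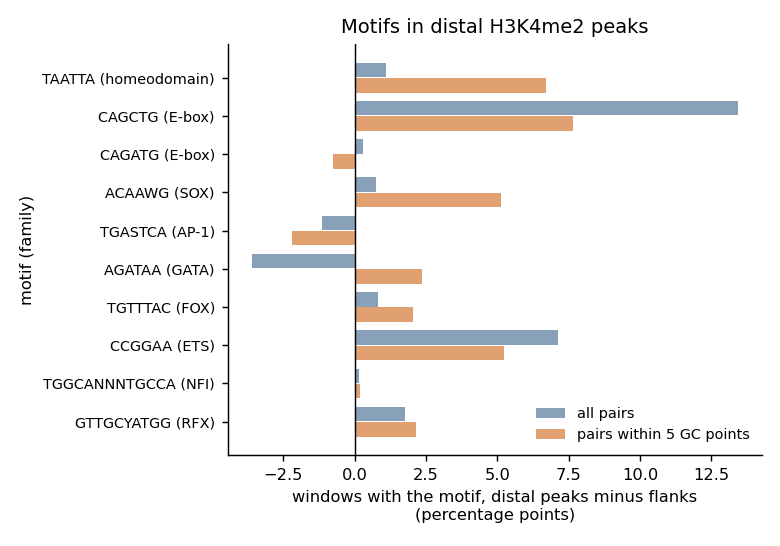
Difference in the percentage of 500 bp windows with each motif, distal peaks minus flanks, in percentage points (x axis), for the 10 motifs and their factor families (y axis). Blue bars are all 15160 pairs and orange bars the 6665 pairs within 5 GC points. CAGCTG is higher in peaks in both sets (13.4 and 7.64), and AGATAA turns from -3.60 to 2.37.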

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

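No test was chosen for this result before or after it was seen. Of the 37511 replicated peaks, 12 lay on 5 sequences outside the assembled chromosomes, which the gene comparisons left out. They stood out because peaks were called in data that no comparison used, and no background level was measured for those sequences. Their enrichment ranged from 2.62 to 13.6 with a median of 9.07, and their median width was 761 bp. No biological explanation was tested.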

How the results depend on the processing

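All alternatives were planned except the matching of domain length on CpG number or gene spacing, which was added after the result was seen. Each replicate's own list and the pooled list kept the direction and the side of the threshold of every promoter, distal and motif result they were run on. For domain length the ribosomal list alone changed sign, between -0.841 and 1.95 percentage points over the replicates' own lists. The added matching left all 32 domain-length results on their side. Of the named domain lengths, 108 of 360 alternatives moved by more than the spread between replicates. With peaks at or above the median enrichment, 3 lists had no marked member and no domain-length value. Read depth is unknown, so what it limits was not assessed. For every change below the cause was not tested, unless the alternative's construction gives it.

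Keeping peaks at or above the median enrichment left 18771 peaks, an overlap of 91.3% for replicate 1 and 96.6% for replicate 2, and 75.2% near starts. An overlap of 1 bp gave 79.3% and 83.5%, and 50% of both peaks 65.1% and 68.1%. Correlation by -log10 p was 0.955. The start-site share was 40.6 to 42.1% over the replicates' own lists, 38.7% in the pooled list and 58.5% within 2.5 kb.

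Promoter differences in percentage points, matched on CpG, were 6.79 for midbrain patterning, 7.29 for neural progenitor, 2.16 for ribosomal, -6.51 for microglia, -14.3 for muscle and -22.0 for liver, all no longer past the threshold. The midbrain share was at its maximum of 100%, so an excess could not have passed there. Hox passed at -33.2, dopaminergic turned to -1.34 and erythroid to 9.91. At or above the median enrichment, forebrain was 3.52 and no longer passed, Hox -39.7 and glia -33.5 passed, and mesenchyme turned to -2.98. Within 2.5 kb muscle was -15.4 and no longer passed, and the other midbrain neuron list 28.8, which passed, as did 28.0 at any coding start.

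Domain-length differences were 6.12 for pan-neuronal genes joined under 3 kb, no longer passing, and -5.01 for glia at or above the median enrichment. Ribosomal turned to -3.63 without joining, -0.841 joined under 3 kb and -0.281 in the longest 10%. Distal excesses matched on spacing were -0.0478 for Hox, no longer passing, and turned to -0.161 for dopaminergic, -0.423 for endothelium, -0.288 for mesenchyme, 0.0861 for muscle and 0.165 for ribosomal. At or above the median enrichment Hox was -0.104, no longer passing, muscle 0.157 and liver 0.0712. Over 5 kb from starts ribosomal was 0.000229. Within 5 GC points CAGATG turned to -0.765 and AGATAA to 2.37, and ACAAWG passed at 5.12.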

Other observations

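The families, noncoding genes and chromosome described in the first 3 paragraphs were chosen after their values were seen, as was the test of forebrain cells in the tissue. The pairs matched on GC content were planned as a second way to compare motifs, and their use as a test of an explanation was chosen after their values were seen. Other gene families also carried long H3K4me2 domains. Families were genes with the same letters at the start of the symbol and at least 10 members, and some hold genes of the fixed lists. Of 172 families with enough marked members, 7 had more genes in the longest 5% than other marked genes and 0 had fewer. Most families were too small for a count of 0 to pass as fewer. The Sox family of transcription factors had 11 of 18 (adjusted p = 1.90e-08), the Pou family 7 of 11 and the protocadherins named Pcdh 7 of 11 (adjusted p = 1.25e-05 for each, Fisher's exact tests). Protocadherins are adhesion molecules, and Pcdh10 had 11.99 kb, Pcdh7 11.5 kb and Pcdh19 11.2 kb. Of the clustered protocadherins, 0 of 11 marked Pcdhga genes were in the longest 5%, and 1 of 12 Pcdha genes, Pcdha12, and 1 of 22 Pcdhb genes, Pcdhb1, were marked at their start. The Wnt receptors of the Fzd family had 5 of 10 (adjusted p = 0.00222, Fisher's exact test), namely Fzd1, Fzd2, Fzd7, Fzd8 and Fzd10, with 11.6 kb at Fzd10. Histone genes had 14 of 60 by gene (adjusted p = 4.99e-05), but these lay in 4 of 32 distinct domains, a share that did not pass (adjusted p = 0.710, Fisher's exact tests), and replicate 2's own list had 10 such genes. The other 6 families passed by distinct domains as well. No family comparison, of domains or of gene starts, was matched on CpG content. Bcl-named genes had 6 of 17 (adjusted p = 0.00347) and Arid-named chromatin genes 4 of 10 (adjusted p = 0.0256, Fisher's exact tests), namely Arid1a, Arid1b, Arid2 and Arid5b. At gene starts, 264 families were tested, of which 88 were marked more often than other genes and 56 less often. Of the latter, 1 of 331 vomeronasal receptor genes was marked against 64.5% of other genes. Keratin-associated protein genes had 1 of 57 marked, against 63.7% of other genes. These were Vmn1r4, in a domain that also reached the start of Nt5c3, and Krtap17-1.

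Long domains also lay at microRNA genes. Of 727 domains of at least 6.64 kb, 58 reached no coding start. Of these 58, 12 held an annotated microRNA gene, against a mean of 0.42 and a highest count of 4 in 100 random placements. Among the 669 long domains that reached a coding start, 36 held 1 (p = 0.000159, Fisher's exact test). The 58 were set apart by the lack of a coding start, and neither comparison was matched on noncoding genes. An excess over other noncoding genes was therefore not tested. The longest of the 12 held Mir9-2, with 30.1 kb on chromosome 13 from 83712826 to 83742900 and 31.4 kb ± 1.86 in the replicates' own lists (SD, n = 2). Mir9-3 lay in 25.3 kb, Mir9-1 in 24.0 kb, Mir124a-2 in 18.2 kb, Mir125b-1 in 14.8 kb, Mir124a-3 in 11.6 kb and Mir124a-1 in 11.05 kb. The miR-9 and miR-124 genes give microRNAs of the developing nervous system. Others of the 12 held Mir129-2, Mir7-2, Mir137, Mir99a with Mirlet7c-1, and Mir3089.

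On chromosome X, 467 of 948 protein-coding genes (49.3%) were marked at their start, against 13476 of 20807 on autosomes (64.8%, p = 1.68e-21, Fisher's exact test). Single autosomes ranged from 52.1% on chromosome 7 and 54.1% on chromosome 14 to 77.6% on chromosome 12. The chromosome X comparison was not matched on CpG content or gene family, so it does not single out the chromosome itself. On chromosome Y the marked genes were Ddx3y, Eif2s3y, Kdm5d and Uty, with the longest domain, 2.23 kb, at Uty. The longest domain that reached no 5′ end of a coding gene record was 35.1 kb on chromosome 8 from 108694954 to 108730083, within Zfhx3, where it reached 2 other coding starts of that gene.

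Forebrain patterning genes carried long domains in tissue labelled midbrain, with 11 of 22 (50%) in the longest 5%. CpG number within 5 kb was argued against as the whole cause, since lists matched on it gave 21.1% (central 95% 4.55 to 36.4). Counting a shared domain more than once was also argued against, since the 11 of 22 distinct domains (50%) compare with 4.64% of other distinct domains (p = 1.03e-09, Fisher's exact test). Forebrain cells in the dissected tissue stay open, since the median enrichment at forebrain starts was 17.9 against 23.5 at midbrain patterning starts, a difference of -5.67 with a permutation p of 0.253. Members went both ways, with 2.27 kb and an enrichment of 11.5 at Foxg1, 18.3 kb and 19.7 at Emx2, and 8.46 kb and 48.4 at Dlx2, and no biological explanation was tested.

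Marked domains at Hox genes were short, with a median of 0.752 kb over the 22 marked genes and 0.501 and 0.719 kb in the own lists of replicates 1 and 2. CpG number was argued against as the cause, since matched lists gave 3.82 kb (central 95% 3.07 to 4.91). Close spacing of gene starts was argued against in the same way, with 2.83 kb (central 95% 2.26 to 3.51). Splitting by the caller was argued against too, since the median was 0.84 kb with peaks closer than 3 kb joined, below the lower quartile of 2.00 kb of other marked genes. Mixing of cells that differ in Hox marking was not tested, nor was any biological explanation.

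The GATA motif AGATAA was less frequent in distal peaks than in flanks by -3.60 percentage points, and CAGCTG more frequent by 13.4. Among pairs within 5 GC points AGATAA was 2.37 points more frequent in peaks, so higher GC content of peaks may account for its lower share. CAGCTG stayed 7.64 points more frequent among those pairs (adjusted p = 9.24e-23, exact McNemar test), which argues against GC content as its whole cause. No biological explanation was tested for either motif.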
